A study of Mus musculus with 15 samples.

How the data were processed

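RNA sequencing had been done on 15 libraries of mouse iKPC pancreatic cancer cells, and each library was placed in its group by its deposited title. In a knockdown experiment of 9 libraries, 3 had Nfat5 knocked down, 3 had Smad3 knocked down and 3 carried a scramble control. In a separate inhibitor experiment of 6 libraries, 3 had received KRN2 and 3 had received DMSO. Per the labels' protocols, RNA was extracted with a Qiagen kit and libraries were made with the NEBNext Ultra RNA kit. The submitters' processing notes name bcl2fastq 2.17, STAR 2.5.2b, featureCounts and Subread 1.5.2, with the build GRCm38 and with no role or order. Whether reads were counted by strand is not given in the sources used here, so reads of a gene and of an overlapping gene on the other strand cannot be told apart. How reads shared by near-identical genes were counted is likewise not given, and values of multigene families (Prl2c2 and Prl2c3, Naip1, the H2 genes) are uncertain.

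For the inhibitor experiment the authors deposited raw whole-number counts per Ensembl gene, with gene positions and lengths in the layout of featureCounts per the file headers. Those files hold 49315 gene identifiers, of which 48970 were matched to a symbol in the reference gene table. For the knockdown experiment the authors deposited a table of 45705 genes in a normalised signal unit, named normalised counts per the file headers. Its library totals lay between 48509800 and 50332300. Each library's values appeared to be gene counts divided by 1 factor, because 33.6 to 39.7% of the values under 5 in a library were the same number to within 0.0000015. After division by that number, the value of 1 read, the totals lay between 36281800 and 58974600. Between 44.5 and 47.5% of the nonzero values then lay within 0.005 of a whole number, so whole reads were not recovered. How fractional values arose is not given in the sources used here. The table had 92 symbols on more than 1 line, which were kept apart by identifier.

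Differential expression in the knockdown experiment was tested with limma 3.58.1 with a mean-variance trend on log2(value + 1). Genes with a value of at least 10 in at least 3 of the 9 libraries were kept, all 9 libraries entered a single fit, and 15540 genes were tested. Fold changes of this experiment are on the log2(value + 1) scale, which understates changes of low genes. The inhibitor experiment was tested with the quasi-likelihood test of edgeR 4.0.16, with TMM factors and filterByExpr, on 15044 genes. A prior count of 2 entered only the log2 CPM with which its replicates were compared. Its levels are given as CPM (counts scaled to library size), and its standard errors are the absolute log2 fold change divided by the square root of F. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a comparison, with a threshold of 0.05. Each table was tested on its own, since the authors scaled only the first. R 4.3.3 and the data.table package (version 1.17.8) were used. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

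Before the data were examined, 32 gene lists with 680 entries were written from general knowledge. They cover TGFβ/SMAD targets, mesenchymal and epithelial genes, matrix genes, YAP/TEAD targets, osmotic NFAT5 targets, KRAS-ERK output, the SMAD, NFAT and RAS genes themselves, NF-κB, interferon, MHC class I and S100 genes. They also cover G1/S and G2/M genes, glycolysis, hypoxia, cholesterol and fatty acid synthesis, ATF4 and ER stress genes, NRF2, AhR and p53 targets, nuclear and mitochondrial respiratory genes, lysosome and ribosome biogenesis genes. Another 5 hold markers of other cells (macrophages and leukocytes, fibroblasts, endothelium, acinar and endocrine cells, and haemoglobin). Of 650 distinct symbols, 649 were matched to an identifier. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes. An estimated correlation and fry served as alternatives, each adjusted over the lists of a comparison. Camera compares a list with the other genes. Fry asks whether the genes of a list move, on balance, in 1 direction and does not compare them with other genes. For members of a list, counts are also given after adjustment over the list alone. Symbols are those of the files, so Ccn1 and Ccn2 appear as Cyr61 and Ctgf in the knockdown table.

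The genes that could be named were also fixed in advance. They were Nfat5, Smad3, Smad2, Smad4, Kras, S100a4 and Ccl2, and the 8 largest rises and 8 largest falls per comparison among genes with a mean level of at least 50 and no overlap between the groups' libraries. By chance, 10% of genes show no overlap between 3 libraries and 3. Up to 4 members of each list with the smallest adjusted p, all members of lists with 10 or fewer, and the 8 largest shared changes per direction and 8 largest opposite changes completed the rule. Fewer are printed, mostly those whose call held under every alternative, a selection made after the values were seen.

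Comparisons against the same scramble libraries share their chance values. Unchanged groups were therefore simulated against those controls in 100 draws, and the overlap of independent lists was computed from the calls. Pearson and Spearman coefficients are across genes, which are not independent replicates. Replicates were checked for duplicates with a chi-square of their counts. It lay between 4.18 and 8.31 per degree of freedom in the inhibitor experiment and between 15.4 and 62.0 in the knockdown experiment, so no pair was the same library. Every comparison was recomputed with other filters, scalings and tests, with a term for the replicate number, and without each library in turn. The knockdown comparisons were also recomputed with other pseudocounts (0.5 and 5) and with only the 2 groups compared. DESeq2 1.42.0 was an alternative for the inhibitor counts. An edgeR test on whole reads had been planned for the knockdown table and was not run, because whole reads were not recovered. In its place, added after seeing the data, edgeR was run on the values divided by the value of 1 read and rounded.

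The tests were run on simulated data with known changes. The simulated knockdown libraries had the totals of the normalised values. All simulated genes had the same dispersion, which was set by hand and not taken from these libraries. For the Nfat5 knockdown comparison, on 15367 simulated genes, limma called 58.2% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 97.0% of those changed 4-fold, and 2 unchanged genes. In the same draw, with no gene changed for the Smad3 knockdown, 0 were called. For KRN2, on 14856 simulated genes, edgeR called 64.2, 91.0 and 93.9% at those sizes and 8 unchanged genes. Gene positions are those of the deposited inhibitor files on GRCm38.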

Results

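The samples were mouse iKPC cells, a pancreatic ductal adenocarcinoma line made with p48-Cre, a tetracycline-controlled mutant Kras allele, rtTA at the ROSA locus and a conditional Trp53 allele, in which doxycycline keeps mutant Kras on. The study asked how NFAT5, a transcription factor known from the response to hypertonic stress, and the SMAD proteins, which carry the TGFβ signal to the nucleus, act together when such cells escape their dependence on mutant KRAS. Cells had been grown with doxycycline at 1 µg/ml. For all 15 libraries doxycycline was then withdrawn and TGFβ given at 0.5 ng/ml for 3 days. The knockdown experiment compared Nfat5 knockdown, Smad3 knockdown and scramble control, and the inhibitor experiment compared KRN2, described as an NFAT5 inhibitor, with DMSO (n = 3 libraries per group). The dose of KRN2 is not given in the sources used here. Totals before scaling were 36281800 to 58974600 per library in the knockdown experiment, and 20506848 to 30244607 counts per library in the inhibitor experiment. Between 20211 and 21936 genes had a value above 0 in the former and between 21452 and 22385 in the latter.

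The targeted genes were read first. Smad3 (chromosome 9, 63646767 to 63757994) fell to 42.9% of its scramble level in the Smad3 knockdown, from 14796 ± 1055 to 6341 ± 457 normalised counts (mean ± SD, n = 3). Its 3 libraries there read 5838, 6731 and 6456, against 15890, 14714 and 13785 in scramble (log2 fold change −1.22 ± 0.09 standard error, limma adjusted p = 1.2e-05). Nfat5 (chromosome 8, 107293470 to 107379517) read 2958, 2895 and 2896 in the Nfat5 knockdown and 6159, 3831 and 3456 in scramble, a mean of 2916 ± 36 against 4482 ± 1465. That difference did not pass the test (log2 fold change −0.57 ± 0.21, limma adjusted p = 0.112, and 0.0592 to 0.254 over all alternatives). The Smad3 knockdown libraries read 4895, 3857 and 6066. Against the Smad3 knockdown the difference in Nfat5 was −0.74 (adjusted p = 0.0242). That call was lost without Nfat5 knockdown 1, 2 or 3 (adjusted p = 0.0577, 0.0584 and 0.0629) and without Smad3 knockdown 1 or 3 (0.0616 and 0.0866). Smad3 in the Nfat5 knockdown differed from scramble by 0.02 (adjusted p = 0.914), and Nfat5 in the Smad3 knockdown by 0.16 (adjusted p = 0.602). With KRN2, Nfat5 fell from 189 ± 21 to 113 ± 6.5 CPM (log2 fold change −0.74 ± 0.06, edgeR adjusted p = 6.1e-08).

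**Figure D1:**
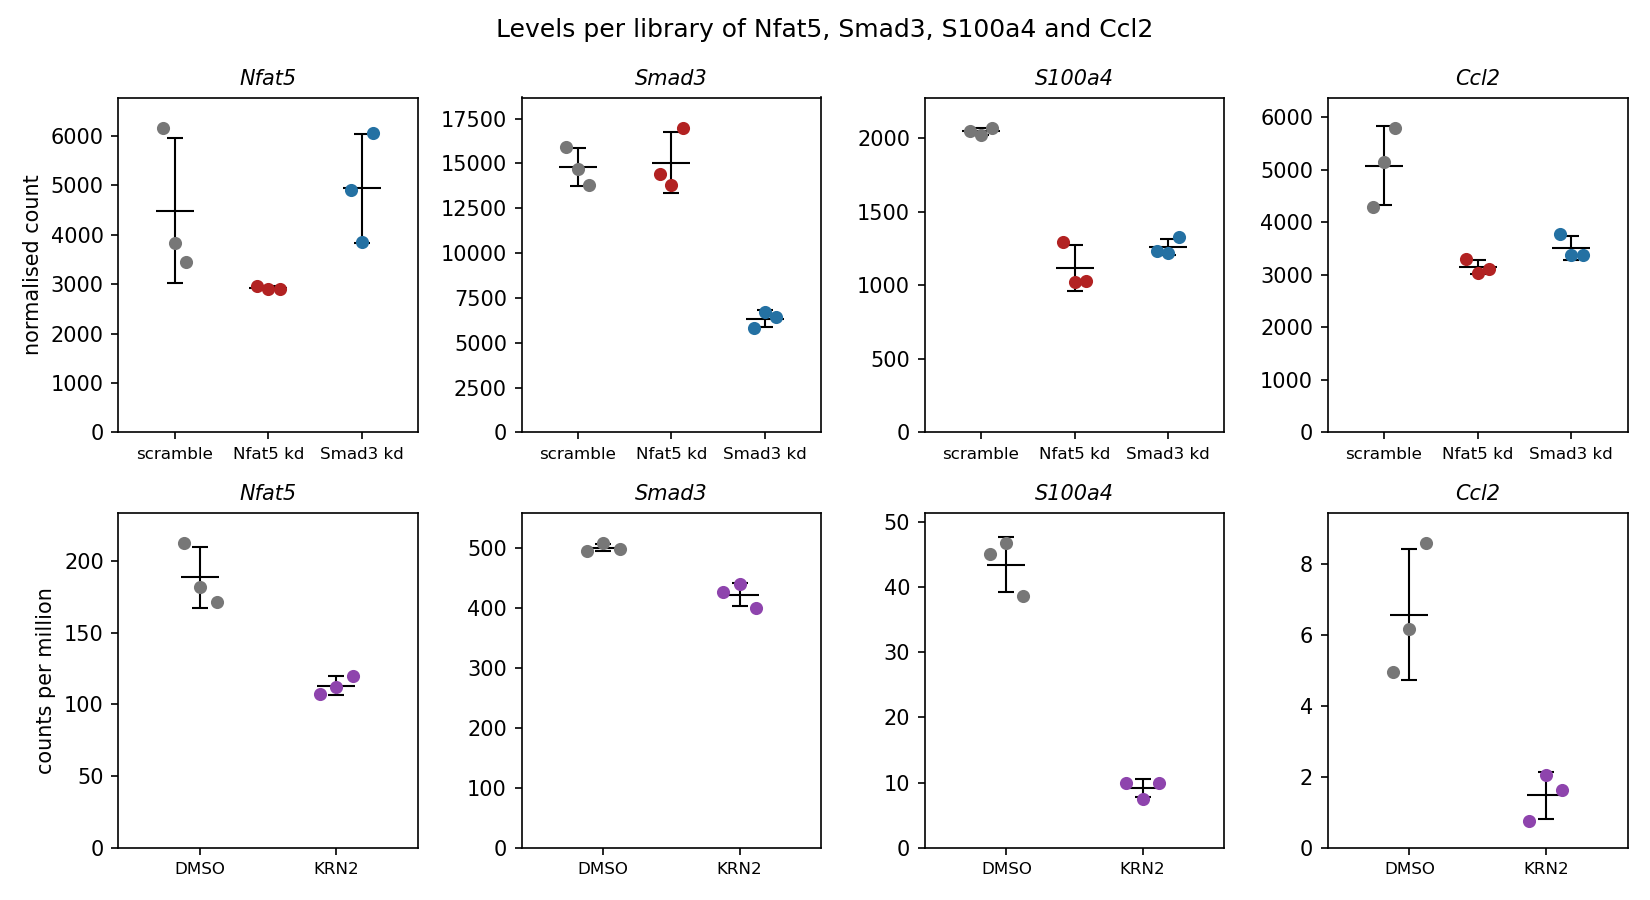
Level of Nfat5, Smad3, S100a4 and Ccl2 in each library, in normalised counts for the knockdown experiment (upper panels; kd, knockdown) and in CPM for the inhibitor experiment (lower panels); points are libraries, horizontal marks are means and error bars are SD (n = 3). The 3 Nfat5 knockdown libraries read 2895 to 2958 for Nfat5, below all 6 others, and scramble replicate 1 stood highest at 6159.

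In the Nfat5 knockdown, Acta2, the smooth muscle actin of myofibroblasts (chromosome 19, 34241090 to 34255336), fell to 34.1% of scramble, from 951 ± 12 to 325 ± 38 normalised counts (log2 fold change −1.55 ± 0.10, adjusted p = 2.4e-04). Sod3, the secreted superoxide dismutase (chromosome 5, 52363791 to 52371418), fell from 206 ± 62 to 29.2 ± 2.9 (log2 fold change −2.74 ± 0.26, adjusted p = 0.00126). Mrc1, the mannose receptor of macrophages and some endothelium, rose from 109 ± 7.5 to 314 ± 8.8 (2.87-fold). In all, 1672 of 15540 genes passed (limma, adjusted p below 0.05), 940 higher and 732 lower, with a median absolute log2 fold change of 0.36. Of these, 60 rose and 44 fell more than 2-fold, and 29 to 59 and 24 to 51 did so without each library in turn. The count of 1672 moved to 538 without Nfat5 knockdown 1, 616 without Nfat5 knockdown 3, 774 without scramble 2, 982 without scramble 1, 1020 without Smad3 knockdown 3 and 1105 without Smad3 knockdown 2. It was 1087 with no filter on low values and 606 with only the groups compared in the fit.

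Among the largest falls were Megf6 (−1.61), Itga11, a collagen-binding integrin subunit (−1.60), Gper1, a membrane oestrogen receptor (−1.55), Runx3, a transcription factor known to act with SMADs (−1.47), and Fmod, a collagen-binding proteoglycan (−1.18). The RNA component of RNase MRP, Rmrp (−2.06), and 5.8S ribosomal RNA, n-R5-8s1 (−1.76), fell too. Both are transcripts without a poly(A) tail, and scramble 1 read highest in each. Among the largest rises were Neto2 (1.81), Tceal8 (1.80), Sprr1a, a component of the cornified envelope (1.86), Plod2, a collagen lysyl hydroxylase (1.67), and Naip1 (1.81). S100a4, a calcium-binding protein of migrating mesenchymal cells (chromosome 3, 90603771 to 90606045), fell by 0.88 on the log2 scale, to 1118 ± 156 from 2047 ± 25 normalised counts. The chemokine Ccl2 (chromosome 11, 82035571 to 82037453) fell by 0.68, to 3149 ± 135 from 5076 ± 756. Kras (−0.06, adjusted p = 0.650), Smad2 (0.12, 0.283) and Smad4 (−0.19, 0.220) did not pass.

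Of 25 G2/M genes, 20 rose and 0 fell, against 24 and 0 adjusted over the list alone (camera adjusted p = 1.4e-15, and adjusted p = 0.211 with an estimated correlation). Hmmr (0.70), the kinesin Kif23 (0.48), the spindle protein Prc1 (0.41) and cyclin B1, Ccnb1 (0.36), were examples. Of 25 G1/S genes, 11 rose and 0 fell (18 and 0 adjusted over the list alone; camera 1.4e-09, and adjusted p = 0.196 with an estimated correlation). They included DNA polymerase alpha, Pola1 (0.52), the ribonucleotide reductase subunits Rrm2 (0.49) and Rrm1 (0.34), and dihydrofolate reductase, Dhfr (0.44). Of 24 genes of cholesterol synthesis, 10 rose and 0 fell, against 12 and 2 adjusted over the list alone (camera 0.00130, and adjusted p = 0.196 with an estimated correlation). Idi1 (0.71), HMG-CoA synthase, Hmgcs1 (0.42), the sterol sensor partner Insig1 (0.38) and Sc5d (0.37) were among them. Fatty acid synthesis gave 5 of 15 higher and 0 lower (6 and 0 adjusted over the list alone; camera 0.0143, and adjusted p = 0.554 with an estimated correlation), with Acsl3 (0.54), the desaturase Scd1 (0.49) and malic enzyme, Me1 (0.35). This call was lost without scramble 3 (adjusted p = 0.226) and under fry (0.0509). Among 20 hypoxia-inducible genes 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera 0.0116, and adjusted p = 0.196 with an estimated correlation). Ero1l, an oxidase of the endoplasmic reticulum (0.70), the pyruvate dehydrogenase kinase Pdk1 (0.66) and the prolyl hydroxylase Egln3 (0.57) rose, and Ddit4 fell (−0.25).

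Of 25 matrix genes 7 fell and 1 rose (13 and 2 adjusted over the list alone; camera 1.9e-05, and adjusted p = 0.228 with an estimated correlation). Collagen chains Col6a3 (−1.08), Col5a3 (−1.07) and Col5a1 (−0.55) and the fibulin Fbln2 (−0.36) fell, whereas Fbln1 rose (0.45). Of 26 mesenchymal genes 4 fell and 0 rose, against 7 and 0 adjusted over the list alone (camera 2.6e-04, and adjusted p = 0.196 with an estimated correlation). Besides Acta2 and S100a4 these were the matrix proteins Sparc (−0.75) and tenascin C, Tnc (−0.53). TGFβ/SMAD targets gave 5 of 28 lower and 2 higher (10 and 4 adjusted over the list alone; camera 0.00873, and adjusted p = 0.196 with an estimated correlation), with the metalloproteinase inhibitor Timp1 at −0.52. YAP/TEAD targets gave 5 of 20 lower and 0 higher, the same counts as adjusted over the list alone (camera 0.00223, and adjusted p = 0.211 with an estimated correlation), with Gadd45b at −0.33. Of 20 genes of the endoplasmic reticulum stress response 4 fell and 0 rose (4 and 1 adjusted over the list alone; camera 0.00316, and adjusted p = 0.303 with an estimated correlation), among them Sdf2l1 (−0.53), Creld2 (−0.39) and Hyou1 (−0.36). Lysosomal and autophagy genes gave 4 of 25 lower and 0 higher (6 and 1 adjusted over the list alone; camera 0.00805, and adjusted p = 0.196 with an estimated correlation), with cathepsin D, Ctsd (−0.28), and the autophagy receptor Sqstm1 (−0.27). Among 27 NF-κB-driven genes 7 fell and 1 rose (8 and 2 adjusted over the list alone; camera 0.0335, and adjusted p = 0.196 with an estimated correlation). The chemokines Ccl7 (−1.33) and Cx3cl1 (−0.54) and complement C3 (−0.58) fell. That list's call was lost without scramble 2 (adjusted p = 0.0538) and without Nfat5 knockdown 2 (0.0629). Nuclear respiratory chain genes gave 3 of 30 lower and 0 higher (7 and 0 adjusted over the list alone; camera 0.0116, and adjusted p = 0.554 with an estimated correlation). This call was lost under fry (0.111), without scramble 3 (0.142) and without Nfat5 knockdown 3 (0.0803).

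Known osmotic targets of NFAT5 did not pass as a list: 3 of 15 fell and 1 rose (4 and 1 adjusted over the list alone; camera adjusted p = 0.272). The taurine transporter Slc6a6 (−0.67), the water channel Aqp1 (−0.59) and aldose reductase, Akr1b3 (−0.35), fell. Transcripts of KRAS-ERK output gave 5 of 25 higher and 3 lower (8 and 5 adjusted over the list alone; camera 0.277). Cyclin D1, Ccnd1 (0.51), and the EGFR ligand Areg (0.55) rose, and Hbegf, another EGFR ligand, fell (−0.27). Epithelial genes gave 4 of 24 higher and 1 lower (also adjusted over the list alone; camera 0.0605). Occludin, Ocln (0.56), and Krt18 (0.28) rose and plakoglobin, Jup, fell (−0.58). The epithelial list passed without scramble 1 (adjusted p = 0.00483) or scramble 2 (0.0471). Markers of macrophages and leukocytes, whose source in these cultures was not tested, gave 1 of 7 higher, Mrc1, and 0 lower (3 and 0 adjusted over the list alone, median 0.29, mean 0.42, camera 0.231, fry 9.4e-04). Beside it, the leukocyte genes Laptm5 (1.54, adjusted p = 0.0947), Aif1 (0.75, 0.399), Cd68 (0.29, 0.0992), Cd14 (−0.15, 0.265), Cd74 (−0.32, 0.212) and Csf1r (−0.67, 0.603) did not pass. Cd14 passed without scramble 3 (−0.26, 0.0239). Of 7 fibroblast markers, which mesenchymal cancer cells share in part, 1 fell and 0 rose (2 and 0 adjusted over the list alone; camera 0.230, fry 9.4e-04). Endothelial markers gave 0 of 5 past the threshold (1 higher and 0 lower adjusted over the list alone; camera 0.640). Their median was −0.51, while fry gave a rise (adjusted p = 0.0198). The acinar marker Cela1 (−0.04, 0.802) and the haemoglobin genes Hba-a1 (0.35 ± 1.34, 0.900) and Hbb-bs (2.92 ± 1.53, 0.247; from 4.75 ± 8.2 to 37.8 ± 39 normalised counts) did not pass.

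Nfat5, unlike Smad3, did not pass in its own knockdown, so the 2 knockdowns were not shown to be of like strength. With that limit, knockdown of Smad3 changed more genes than that of Nfat5. H19, an imprinted noncoding RNA (chromosome 7, 142575529 to 142578143), fell to 5.26% of scramble, from 1810 ± 312 to 95.3 ± 0.76 normalised counts (log2 fold change −4.22 ± 0.12, adjusted p = 2.0e-07). Acta2 fell to 10.5%, from 951 ± 12 to 99.9 ± 6.9 (−3.24 ± 0.10). Itgb6, an epithelial integrin subunit (chromosome 2, 60598292 to 60722643), rose from 145 ± 20 to 1211 ± 45 (3.06 ± 0.11, adjusted p = 3.3e-07). Ceacam19 (chromosome 7, 19875742 to 19887965) rose from 0.588 ± 0.51 to 127 ± 0.87. In all, 4801 of 15540 genes passed (limma), 2556 higher and 2245 lower, with a median absolute log2 fold change of 0.46. More than 2-fold rises and falls numbered 579 and 408. None of the alternatives moved the count of 4801 by over 1.5 times, and leaving out each library gave 3742 to 4703 genes. With values of at least 50 in 3 libraries, rises and falls of more than 2-fold numbered 431 and 268.

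Large rises included the fructose aldolase Aldob (5.18, from 4.01 to 181 normalised counts), the mucin Muc13 (4.97), the galectin Lgals2 (4.72), the brush border protocadherin Cdhr2 (4.47) and the guanylate cyclase Gucy2c (4.02). Carboxypeptidase M, Cpm, rose too (4.73). Large falls included Runx3 (−3.79), Angpt4 (−3.58), Cd40, a receptor of the tumour necrosis factor family (−3.56), Fmod (−3.28) and the receptor tyrosine kinase Fgfr1 (−3.01). S100a4 fell by 0.70 on the log2 scale and Ccl2 by 0.52 (adjusted p = 3.5e-04 and 0.00350). Kras (−0.15, 0.162), Smad2 (−0.09, 0.370) and Smad4 (−0.10, 0.475) did not pass.

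Mesenchymal genes fell in 20 of 26 cases and rose in 1, the same counts as adjusted over the list alone (camera adjusted p = 2.1e-09, and adjusted p = 0.0682 with an estimated correlation). The PDGF receptor Pdgfrb (−2.16), the gelatinase Mmp9 (−1.61) and the fibronectin receptor subunit Itga5 (−0.82) were among them. Of 28 TGFβ/SMAD targets 18 fell and 5 rose (20 and 6 adjusted over the list alone; camera 3.4e-05, and adjusted p = 0.0988 with an estimated correlation). Serpine1, the plasminogen activator inhibitor (chromosome 5, 137061504 to 137072268), fell from 83869 ± 6780 to 31282 ± 1334 normalised counts, and nerve growth factor, Ngf, fell by 1.53, while Itgb6, also on this list, rose. Of 25 matrix genes 15 fell and 2 rose, as they did adjusted over the list alone (camera 3.4e-05, and adjusted p = 0.278 with an estimated correlation), with Col5a3 (−2.86), Col8a1 (−1.11) and Col5a1 (−0.75). YAP/TEAD targets gave 13 of 20 lower and 1 higher (14 and 1 adjusted over the list alone; camera 1.4e-05, and adjusted p = 0.162 with an estimated correlation), with Amotl2 (−0.82), Cyr61 (−0.66) and Lats2 (−0.52). Transcripts of KRAS-ERK output gave 15 of 25 lower and 5 higher (16 and 5 adjusted over the list alone; camera 3.4e-05, and adjusted p = 0.234 with an estimated correlation). The ERK phosphatase Dusp4 (−1.11), the chromatin protein Hmga2 (−1.07), Ier3 (−1.02) and Hbegf (−0.75) fell. Of the SMAD, NFAT and RAS genes themselves 9 of 22 fell and 2 rose (10 and 2 adjusted over the list alone; camera 0.00915, and adjusted p = 0.278 with an estimated correlation), with Smad3 itself and the ligand Tgfb3 (−0.79).

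Epithelial genes rose in 17 of 24 cases and fell in 2 (19 and 2 adjusted over the list alone; camera 1.1e-07, and adjusted p = 0.181 with an estimated correlation). Occludin (1.45), desmoplakin, Dsp (1.42), the protease inhibitor Spint2 (0.95) and the epithelial transcription factor Elf3 (1.18 ± 0.04; chromosome 1, 135253575 to 135258568) rose. Genes of cholesterol synthesis rose in 21 of 24 cases and fell in 0, as they did adjusted over the list alone (camera 6.1e-12). It was the only list of this comparison whose call held with an estimated correlation (adjusted p = 0.0437 with an estimated correlation). Tm7sf2 (1.23), Hmgcs1 (0.88), squalene epoxidase, Sqle (0.72), and squalene synthase, Fdft1 (0.71), were examples. Fatty acid synthesis gave 10 of 15 higher and 0 lower (11 and 0 adjusted over the list alone; camera 1.1e-05, and adjusted p = 0.304 with an estimated correlation), with Scd1 (1.16), Acsl3 (1.13) and Fads1 (0.86). Endoplasmic reticulum stress genes fell in 10 of 20 cases and rose in 0 (11 and 0 adjusted over the list alone; camera 5.4e-05, and adjusted p = 0.234 with an estimated correlation). ATF4 and stress response genes gave 11 of 25 lower and 4 higher (12 and 4 adjusted over the list alone; camera 0.0204, and adjusted p = 0.304 with an estimated correlation). The glutathione-degrading enzyme Chac1 (−0.82), Atf5 (−0.78) and Ddit3 (−0.53) fell and stanniocalcin, Stc2, rose (0.94). Ribosome biogenesis genes fell in 10 of 25 cases and rose in 0 (11 and 0 adjusted over the list alone; camera 6.9e-04, and adjusted p = 0.278 with an estimated correlation), with Rrp12 at −0.44. Of 25 G1/S genes 9 fell and 1 rose, also adjusted over the list alone (camera 0.0238, and adjusted p = 0.429 with an estimated correlation), with the replicative helicase subunit Mcm4 at −0.43. That call was lost without scramble 3 (adjusted p = 0.0936) and without Smad3 knockdown 3 (0.0824). G2/M genes gave 3 of 25 higher and 1 lower (3 and 0 adjusted over the list alone; camera 0.350) and passed without scramble 3 (0.00536).

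NF-κB-driven genes went both ways, with 10 of 27 lower and 6 higher (also adjusted over the list alone; camera 0.220, fry 1.3e-04). Interleukin 1 alpha, Il1a (−2.39), Ccl7 (−1.35) and C3 (−1.13) fell and the adhesion molecule Vcam1 rose (0.60). Osmotic NFAT5 targets gave 4 of 15 higher and 4 lower (also adjusted over the list alone; camera 0.639), with Aqp1 higher (0.74). Of 7 macrophage and leukocyte markers 3 rose and 0 fell (camera 0.0845, fry 3.0e-04), Mrc1 (1.06) and Cd14 (0.55) among them. The third, Laptm5 (1.78, adjusted p = 0.0306), did not pass without scramble 2 (0.0833), scramble 3 (0.0897), Smad3 knockdown 1 (0.0515), 2 (0.0970) or 3 (0.0764), or with no filter on low values (0.0512). Of 7 fibroblast markers 1 rose, the muscle filament desmin, Des (2.74), and 2 fell, Pdgfrb and Col1a1 (−0.45). Their median was −0.13 and their mean 0.07 (camera 0.442, fry 1.9e-04, lower). Endothelial markers gave 1 of 5 higher and 1 lower (camera 0.553), and the acinar marker Cela1 fell (−0.84, adjusted p = 3.6e-05).

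**Figure D2:**
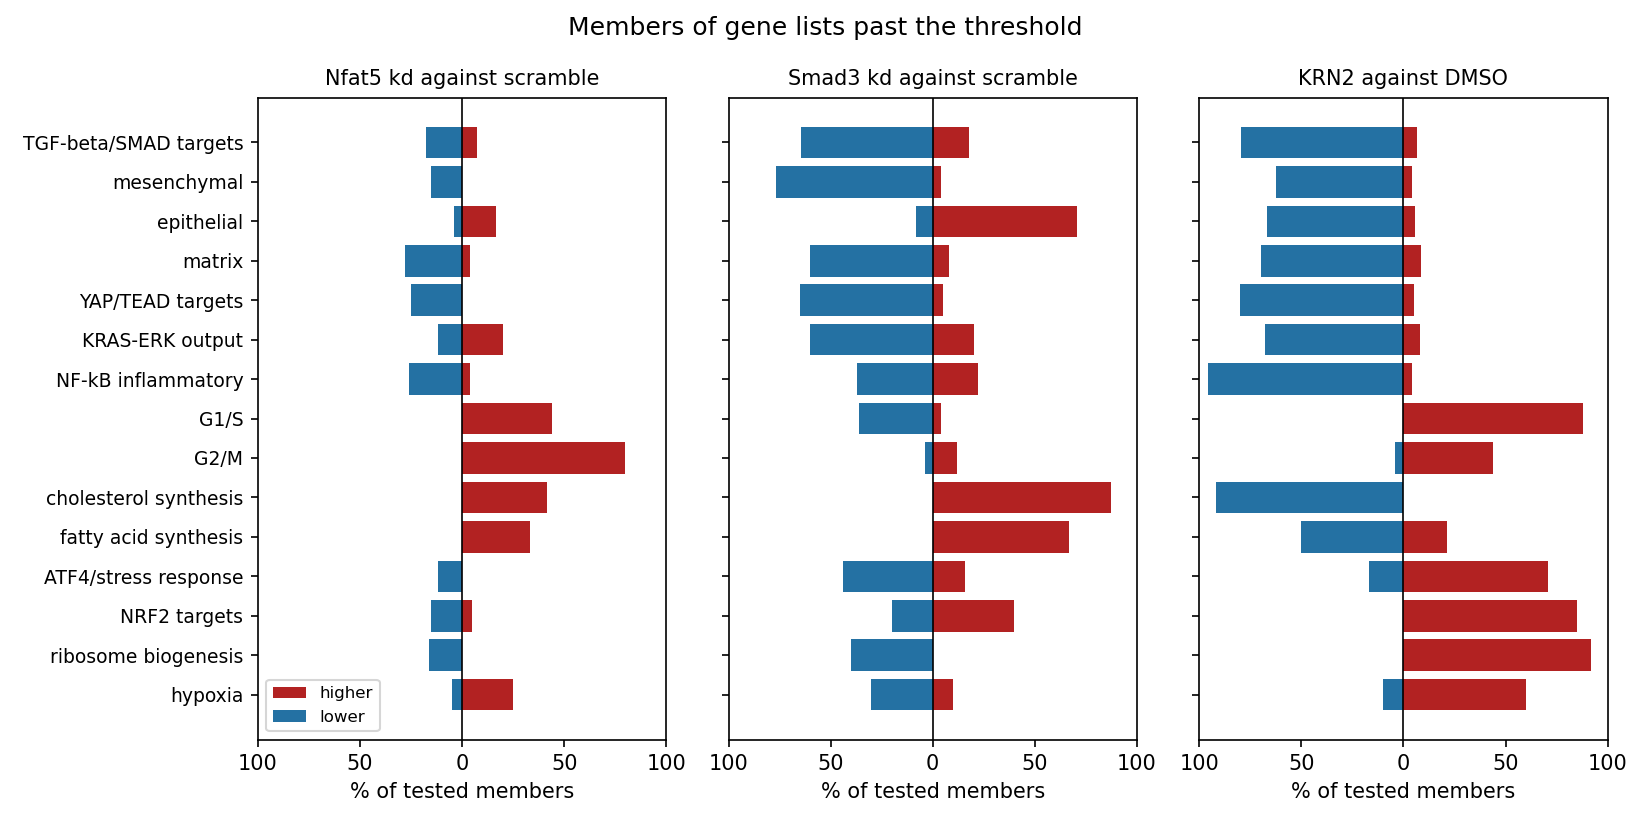
Share of the tested members of 15 gene lists that passed the threshold, higher (red, to the right) or lower (blue, to the left), in Nfat5 knockdown (kd) and Smad3 knockdown against scramble (limma) and in KRN2 against DMSO (edgeR); the horizontal axis is the percentage of tested members. Of 24 genes of cholesterol synthesis, 10 rose in the Nfat5 knockdown, 21 rose in the Smad3 knockdown and 22 fell with KRN2.

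Compared directly, H19 was 3.92 higher on the log2 scale in the Nfat5 than in the Smad3 knockdown, Acta2 1.69, Pdgfrb 1.89 and Serpine1 1.17. Lower in the Nfat5 knockdown were Itgb6 (−2.49) and Elf3 (−1.10). In all 5132 of 15540 genes differed (limma), 2487 higher and 2645 lower in the Nfat5 knockdown, 369 and 534 of them by more than 2-fold. The targeted Smad3 differed by 1.24.

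KRAS-ERK output was higher in the Nfat5 knockdown for 19 of 25 members and lower for 3 (19 and 4 adjusted over the list alone; camera adjusted p = 1.2e-07, and adjusted p = 0.156 with an estimated correlation), with Hmga2 (1.26), Dusp4 (0.92) and Ccnd1 (0.54). G1/S genes were higher for 19 of 25 and lower for 0 (21 and 0 adjusted over the list alone; camera 4.1e-09, and adjusted p = 0.156 with an estimated correlation), with Mcm4 at 0.66. G2/M genes were higher for 17 of 25 and lower for 0 (22 and 0 adjusted over the list alone; camera 1.2e-07, and adjusted p = 0.443 with an estimated correlation), with the checkpoint kinase Bub1 (0.67) and Ccnb1 (0.49). Higher too were mesenchymal genes (13 of 26, 3 lower, and 15 and 3 adjusted over the list alone; camera 1.2e-04, and adjusted p = 0.156 with an estimated correlation). TGFβ/SMAD targets were higher for 14 of 28 and lower for 4 (15 and 4 adjusted over the list alone; camera 0.00244, and adjusted p = 0.156 with an estimated correlation). Hypoxia genes were higher for 11 of 20 and lower for 1 (13 and 2 adjusted over the list alone; camera 0.00244, and adjusted p = 0.156 with an estimated correlation), with the angiogenic factor Vegfa at 0.43. For YAP/TEAD targets 10 of 20 were higher and 1 lower (11 and 1 adjusted over the list alone; camera 0.00687, and adjusted p = 0.367 with an estimated correlation). Ribosome biogenesis genes were higher for 9 of 25 and lower for 1 (10 and 1 adjusted over the list alone; camera 0.00570, and adjusted p = 0.443 with an estimated correlation). For matrix genes, higher in 10 of 25 and lower in 1, also adjusted over the list alone (camera 0.0319, and adjusted p = 0.582 with an estimated correlation), the call was lost without Smad3 knockdown 1 (0.104), without Nfat5 knockdown 3 (0.0891) and after quantile normalisation (0.0502).

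Epithelial genes were lower in the Nfat5 knockdown for 15 of 24 and higher for 1 (16 and 2 adjusted over the list alone; camera 1.4e-06, and adjusted p = 0.185 with an estimated correlation), with Dsp at −1.24. Cholesterol synthesis was lower for 18 of 24 and higher for 1 (22 and 1 adjusted over the list alone; camera 9.2e-08, and adjusted p = 0.139 with an estimated correlation), with Tm7sf2 (−1.17) and Sqle (−0.50). Fatty acid synthesis was lower for 10 of 15 and higher for 0, also adjusted over the list alone (camera 1.2e-04, and adjusted p = 0.443 with an estimated correlation), with Scd1 at −0.67. Nuclear respiratory chain genes were lower for 9 of 30 and higher for 2 (14 and 2 adjusted over the list alone; camera 0.00238, and adjusted p = 0.579 with an estimated correlation). Osmotic NFAT5 targets, as a list, did not pass camera (5 of 15 higher, 7 lower; 5 and 8 adjusted over the list alone; adjusted p = 0.298, fry 0.00654). Of its members, Aqp1 (−1.33) and Slc6a6 (−0.81) were lower in the Nfat5 knockdown. Of the marker lists, macrophage and leukocyte markers gave 1 of 7 higher and 2 lower (camera 0.983), and fibroblast markers 1 of 7 higher, Pdgfrb, and 1 lower, Des (−2.13; 2 and 2 adjusted over the list alone; camera 0.997).

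Both knockdowns lowered Acta2 (−1.55 in the Nfat5 and −3.24 in the Smad3 knockdown), Sod3 (−2.74 and −2.90), Runx3 (−1.47 and −3.79), Itga11 (−1.60 and −1.52), Fmod (−1.18 and −3.28) and Ccl7 (−1.33 and −1.35). Rmrp (−2.06 and −1.75) and n-R5-8s1 (−1.76 and −1.64) fell in both as well. Both raised Cdh17, an intestinal cadherin (1.13 and 1.52), Sprr1a (1.86 and 2.32), Tmem132c (1.49 and 1.16) and Naip1 (1.81 and 1.65). In all 773 genes passed in both with the same sign, 380 higher and 393 lower, and 108 with opposite signs. Opposite were the ketogenic enzyme Hmgcs2 (−0.80 and 2.69) and Csn3 (0.97 and −1.05).

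Independent lists of these sizes would share 260.4 genes the same way (154.6 higher and 105.7 lower) and 256.2 the opposite way. Unchanged groups simulated against the same scramble libraries shared 0.03 on average over 100 draws, and 2 at most. Such groups have few calls to share, so that number cannot show how many of the 773 the common controls added. Across the 15540 genes the fold changes had a Pearson r of 0.344 (Spearman rho 0.331), against a simulated mean of 0.471 (central 95% of draws −0.431 to 0.861) for unchanged groups. Their covariance was 0.0944 against a simulated 0.0620 (−0.0232 to 0.147), a difference of 0.0324, and both observed values lay inside the simulated ranges. With 3 scramble libraries the controls cannot be split, and part of the excess of shared calls may come from them. The count of 773 moved to 294 without Nfat5 knockdown 1, 356 without Nfat5 knockdown 3, 428 without scramble 2, 451 without Smad3 knockdown 3, 485 without Smad3 knockdown 2, 506 without scramble 1 and 508 without Nfat5 knockdown 2, and to 499 with no filter on low values.

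With KRN2 the chemokine Cxcl1 (chromosome 5, 90891241 to 90893115) fell from 17.2 ± 6.4 to 1.33 ± 0.14 CPM (log2 fold change −3.69 ± 0.26, edgeR adjusted p = 3.1e-09), and Stra6, the retinol uptake receptor (chromosome 9, 58063788 to 58153996), from 36.7 ± 3.0 to 2.90 ± 0.30 CPM (−3.66 ± 0.10, 6.2e-14). S100a4 fell to 21.1% of DMSO, from 43.4 ± 4.3 to 9.17 ± 1.4 CPM (−2.24 ± 0.10), and Ccl2 fell to 22.5% (−2.15 ± 0.26). Ccl2 was low in the DMSO libraries (4.97 to 8.59 CPM), below S100a4. In scramble it stood above S100a4 (4287 to 5793 against 2020 to 2070 normalised counts), so its baseline differed between the experiments. Ugt2b34, a glucuronosyltransferase (chromosome 5, 86889767 to 86906937), rose from 21.4 ± 1.5 to 245 ± 9.8 CPM (3.52 ± 0.06), and asparagine synthetase, Asns (chromosome 6, 7675169 to 7693254), from 99.8 ± 2.2 to 291 ± 7.2 (1.55 ± 0.04). In all 6523 of 15044 genes passed (edgeR), 3243 higher and 3280 lower, with a median absolute log2 fold change of 0.37. Rises of more than 2-fold numbered 206 and falls 606. No alternative moved the count of 6523 by over 1.5 times, and leaving out each library gave 5743 to 6171. With at least 50 counts in 3 libraries, rises and falls of more than 2-fold numbered 125 and 353.

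Other large falls were Lgr5, a receptor of R-spondins (−3.65), osteoprotegerin, Tnfrsf11b (−3.58), the cytokine Csf2 (−3.40), the gel-forming mucin Muc5ac (−3.22) and Sprr1a (−3.38). Other large rises were the aldo-keto reductase Akr1b7 (4.03), Aldh1l2, a mitochondrial enzyme of folate metabolism (3.25), Angptl6 (3.31), the glycerol channel Aqp9 (3.31) and Trp53cor1, a noncoding RNA induced by p53 (3.20). Kras fell by 0.41 (adjusted p = 3.6e-06) and Smad3 by 0.24 (1.2e-04), from 501 ± 6.3 to 423 ± 20 CPM. Smad2 (−0.07, 0.236) and Smad4 (−0.09, 0.122) did not pass. Smad4 passed with a filter of at least 50 counts in 3 libraries (−0.11, 0.0477).

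NF-κB-driven genes fell in 22 of 23 cases and rose in 1, also adjusted over the list alone (camera adjusted p = 5.1e-20, and adjusted p = 0.103 with an estimated correlation). The feedback inhibitors Tnfaip3 (−1.73) and Nfkbia (−1.55), Birc3 (−1.40) and Vcam1 (−1.73) fell. Of 29 TGFβ/SMAD targets 23 fell and 2 rose, also adjusted over the list alone (camera 3.2e-11, and adjusted p = 0.144 with an estimated correlation), with Ltbp2 at −2.09. YAP/TEAD targets fell in 16 of 20 cases and rose in 1, also adjusted over the list alone (camera 5.7e-16). That call held with an estimated correlation (adjusted p = 0.0234 with an estimated correlation), as did those of the mesenchymal and NRF2 lists and no other. Tissue factor, F3 (−1.69), Ankrd1 (−1.59), Ccn1 (−1.10) and Ccn2 (−0.95) fell. Mesenchymal genes fell in 15 of 24 cases and rose in 1, also adjusted over the list alone (camera 2.9e-10, and adjusted p = 0.0325 with an estimated correlation), with Tnc (−2.44), vimentin, Vim (−0.75), and the repressor Zeb1 (−0.73). Of 23 matrix genes 16 fell and 2 rose (17 and 2 adjusted over the list alone; camera 2.6e-11, and adjusted p = 0.0588 with an estimated correlation), with Col8a1 (−2.52), Col6a2 (−2.07) and Col6a1 (−1.66). Epithelial genes fell as well, in 12 of 18 cases, and rose in 1, also adjusted over the list alone (camera 1.4e-05, and adjusted p = 0.139 with an estimated correlation), with the keratin Krt7 (−1.35) and Dsp (−0.92). KRAS-ERK output gave 17 of 25 lower and 2 higher (17 and 3 adjusted over the list alone; camera 2.3e-04, and adjusted p = 0.103 with an estimated correlation), with the ERK phosphatase Dusp5 (−0.87) and Hbegf (−0.74).

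Cholesterol synthesis genes fell in 22 of 24 cases and rose in 0, also adjusted over the list alone (camera 9.7e-14, and adjusted p = 0.185 with an estimated correlation). The LDL receptor, Ldlr (−0.89), lanosterol demethylase, Cyp51 (−0.88), Fdft1 (−0.81) and Hmgcs1 (−0.78) were examples. Osmotic NFAT5 targets fell in 7 of 14 cases and rose in 1, also adjusted over the list alone (camera 0.00165, and adjusted p = 0.103 with an estimated correlation), with Aqp1 (−1.42) and the insulin receptor substrate Irs1 (−1.29). S100 genes fell in 10 of 12 cases and rose in 0, also adjusted over the list alone (camera 4.8e-10, and adjusted p = 0.0923 with an estimated correlation), with S100a10 at −1.26. Of the SMAD, NFAT and RAS genes 14 of 22 fell and 1 rose, also adjusted over the list alone (camera 1.2e-04, and adjusted p = 0.103 with an estimated correlation), with Nfatc2 at −1.26.

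ATF4 and stress response genes rose in 17 of 24 cases and fell in 4 (18 and 4 adjusted over the list alone; camera 1.2e-27, and adjusted p = 0.0595 with an estimated correlation). Besides Asns these were Atf5 (1.85) and the serine synthesis enzyme Phgdh (1.26). NRF2 targets rose in 17 of 20 cases and fell in 0, also adjusted over the list alone (camera 1.2e-17, and adjusted p = 0.0234 with an estimated correlation), with the quinone reductase Nqo1 (1.79), the glutathione transferase Gsta4 (1.54), Gclc, which makes the glutathione precursor (1.03), and the cystine transporter Slc7a11 (1.04). Ribosome biogenesis genes rose in 23 of 25 cases and fell in 0, also adjusted over the list alone (camera 4.0e-08, and adjusted p = 0.0848 with an estimated correlation), with nucleolin, Ncl (0.56), and nucleophosmin, Npm1 (0.49). G1/S genes rose in 22 of 25 cases and fell in 0 (23 and 0 adjusted over the list alone; camera 5.2e-06, and adjusted p = 0.159 with an estimated correlation), with the uracil glycosylase Ung (0.75) and the licensing factor Cdt1 (0.46). Hypoxia genes rose in 12 of 20 cases and fell in 2, also adjusted over the list alone (camera 5.2e-06, and adjusted p = 0.150 with an estimated correlation), with Ak4 (1.66), Egln3 (0.98) and the glucose transporter Slc2a1 (0.73). Nuclear respiratory chain genes rose in 16 of 30 cases and fell in 0 (17 and 0 adjusted over the list alone; camera 0.00259, and adjusted p = 0.358 with an estimated correlation). Lysosomal and autophagy genes rose in 12 of 25 cases and fell in 5, also adjusted over the list alone (camera 0.0133, and adjusted p = 0.358 with an estimated correlation), with acid alpha-glucosidase, Gaa, at 0.83. G2/M genes rose in 11 of 25 cases and fell in 1 (12 and 1 adjusted over the list alone; camera 0.0402, and adjusted p = 0.661 with an estimated correlation). The G2/M call was lost without DMSO 2 (0.117), DMSO 3 (0.0881) or KRN2 3 (0.146) and under fry (0.160). Macrophage and leukocyte markers gave 0 of 7 higher and 1 lower, Cd14 (−0.71; camera 0.423, fry 2.3e-04). Fibroblast markers gave 1 of 6 higher and 3 lower (camera 0.278, fry 0.0225, lower) and endothelial markers 0 of 5 higher and 3 lower (camera 0.196, fry 0.00416, lower). Of 3 acinar and endocrine markers Try5, a trypsinogen, rose (2.89) and 0 fell (2 and 0 adjusted over the list alone).

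KRN2 and the Nfat5 knockdown lowered S100a4 (−2.24 and −0.88), the organic anion transporter Slco4a1 (−2.45 and −0.90), the semaphorin co-receptor Nrp2 (−0.79 and −0.81), the small heat shock protein Cryab (−0.91 and −0.84) and Col6a3 (−0.77 and −1.08) alike in direction. Both raised Sec16b (1.58 and 1.01), Prl2c3 (1.18 and 1.68) and Ero1l (0.64 and 0.70). Opposite were Sprr1a (−3.38 and 1.86), Lgr5 (−3.65 and 1.12), Tmigd1 (−2.50 and 1.11) and Il5ra (−1.73 and 1.01). Of 13744 genes tested in both experiments, which share no controls, 544 passed in both with the same sign (262 higher, 282 lower), where independent lists would share 370.1 (212.9 and 157.2). Fisher's exact test gave p = 1.0e-04 for the genes higher in both and 8.9e-28 for those lower in both, with genes taken as independent, which they are not. Another 367 passed with opposite signs, where independent lists would share 370.2. Of these, 238 were lower with KRN2 and higher in the Nfat5 knockdown, and 129 the reverse. Of the 922 genes higher in the Nfat5 knockdown, 262 were thus higher and 238 lower with KRN2. Of the 680 lower there, 282 were lower and 129 higher with KRN2, so agreement in direction lay mainly among the falls. Across genes the fold changes had a Pearson r of 0.0247 and a Spearman rho of 0.0738, and r lay between 0.0113 (without DMSO 3) and 0.0454 (without KRN2 1) when each library was left out (0.0129 without Nfat5 knockdown 1, 0.0404 without DMSO 1). KRN2 and the Smad3 knockdown shared 1386 genes the same way (607 higher, 779 lower), where independent lists would share 1040. They moved 1174 the opposite way (413 higher and 761 lower with KRN2), where independent lists would also share 1040. Of genes higher in the Smad3 knockdown, more were thus lower with KRN2 (761) than higher (607). For this pair r was 0.0191 and rho 0.0470. That r was 0.00392 without DMSO 3, 0.00557 without Smad3 knockdown 1, 0.00906 without KRN2 1, 0.0352 without KRN2 2 and 0.0372 without DMSO 2. The count of 544 moved to 195 without Nfat5 knockdown 1, 224 without Nfat5 knockdown 3, 260 without scramble 2, 346 without scramble 1, 352 without Nfat5 knockdown 2 and 357 without Smad3 knockdown 3, and to 361 with no filter on low values in the knockdown table.

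**Figure D3:**
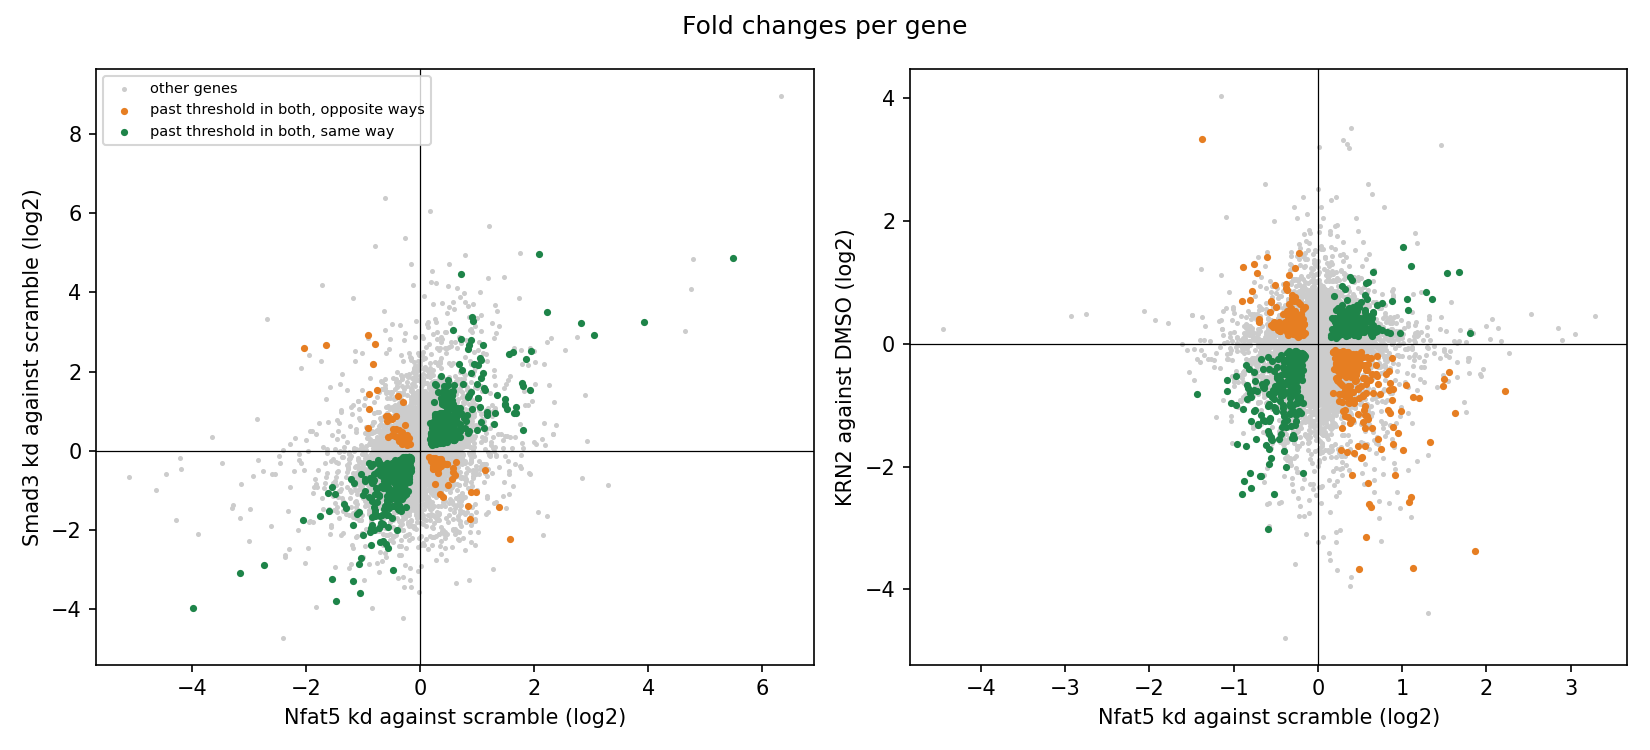
Log2 fold change of each gene in Nfat5 knockdown (kd) against scramble (horizontal axis) set against that in Smad3 knockdown (left, vertical axis, 15540 genes) and in KRN2 against DMSO (right, vertical axis, 13744 genes); green points passed in both comparisons the same way (773 left, 544 right), orange points in both in opposite ways (108 left, 367 right) and grey points are all other genes. Pearson r across genes was 0.344 on the left, where scramble libraries are shared, and 0.0247 on the right.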

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

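The edgeR test on rounded rescaled values, the leave-one-out counts and correlations of KRN2 with either knockdown, and all alternatives of the genes shared by KRN2 and the Smad3 knockdown were chosen after the data were seen, and every other alternative before. An edgeR test on whole reads was not run, because whole reads were not recovered. The counts of genes past the threshold for the Smad3 knockdown, for the knockdowns against each other and for KRN2 stayed within 1.5 times under every alternative (with DESeq2, 5844 genes for KRN2). On rounded rescaled values edgeR called 1616, 4779 and 5117 genes for Nfat5 knockdown, Smad3 knockdown and their difference, and 1547 (92.5%), 4687 (97.6%) and 4969 (96.8%) of the limma calls were among them. The Nfat5 knockdown count was 1087 with no filter (27289 genes tested instead of 15540) and 606 with only the groups compared in the fit, which estimates the spread from fewer libraries. With no filter in the knockdown table, genes shared the same way numbered 499 for both knockdowns and 361 for KRN2 and Nfat5 knockdown. The r between KRN2 and the Nfat5 knockdown was 0.0362 with values of at least 50 in 3 knockdown libraries and 0.0119 with at least 50 counts in 3 inhibitor libraries, and that between KRN2 and the Smad3 knockdown was −0.00182 with no filter on counts. The cause was not tested for these correlations.

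Without each library in turn, genes changed ranged from 538 to 1851 (Nfat5 knockdown), 3742 to 4703 (Smad3 knockdown), 3828 to 5701 (their difference) and 5743 to 6171 (KRN2). Genes shared the same way ranged from 294 to 775 (both knockdowns), 195 to 607 (KRN2 and Nfat5 knockdown) and 1125 to 1353 (KRN2 and Smad3 knockdown). Correlations ranged from 0.277 to 0.428, 0.0113 to 0.0454 and 0.00392 to 0.0372 in that order. The lowest 2 counts for the Nfat5 knockdown came without its replicates 1 (538) and 3 (616), which leaves a group of 2 libraries. Lists past camera ranged from 11 to 16, 12 to 14, 12 to 14 and 20 to 22. Of the limma or edgeR calls on all libraries, 31.0 to 77.9% (Nfat5 knockdown), 76.2 to 94.7% (Smad3 knockdown), 72.6 to 98.8% (their difference) and 85.5 to 89.4% (KRN2) were kept. Of the genes named in the text 76 to 76, 82 to 83, 21 to 22 and 81 to 81 kept theirs, out of 76, 83, 22 and 81. Those counts overstate how stable a call is, because from the genes open to naming mostly ones that kept their call under the alternatives were picked.

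With an estimated correlation the lists past the threshold fell from 13, 13, 13 and 21 to 0, 1, 0 and 3, as that test allows for correlated members. Under fry, which does not compare a list with other genes, 20 lists passed for the Smad3 knockdown and 20 for the difference of the knockdowns. Endothelial markers in the Nfat5 knockdown (fry, higher, adjusted p = 0.0198), fibroblast markers in the difference (fry, higher, 0.0289) and mitochondrial genes in the Nfat5 knockdown without scramble replicate 1 (lower, 0.0441, against 0.602, lower, without Nfat5 knockdown replicate 1, the highest) took the direction opposite to camera's in all libraries, none of which had passed; the cause was not tested. In all, alternatives left 387 of 420 list results for the Nfat5 knockdown, 396 of 420 for the Smad3 knockdown, 392 of 420 for the difference and 302 of 330 for KRN2 as they were. The others lost the threshold in 20, 14, 16 and 22 cases, passed it in 11, 10, 11 and 6 and turned in 2, 0, 1 and 0. Results of named genes stayed as they were in 1704 of 1705, 1645 of 1651, 432 of 437 and 1088 of 1091 cases, were lost in 0, 6, 5 and 0 and passed in 1, 0, 0 and 3.

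The replicate numbers did not pair the libraries: deviations from the group mean of same-numbered libraries correlated at −0.196 to 0.191 in the knockdown experiment (3 of 9 pairs above 0.1) and at −0.0320 to 0.0668 in the inhibitor experiment (0 of 3). Libraries of unlike number correlated at −0.295 to 0.275 (5 of 18 pairs above 0.1) and at −0.0720 to 0.0921 (0 of 6). Smad3 knockdown 2 with Nfat5 knockdown 3 (0.275) and scramble 2 with Nfat5 knockdown 3 (0.256) were the highest. Scramble 2 with Smad3 knockdown 2 gave 0.178, so all pairs of these libraries correlated. All pairs of scramble 3, Smad3 knockdown 1 and Nfat5 knockdown 2 did too (0.131 to 0.159). Those of scramble 1, Smad3 knockdown 3 and Nfat5 knockdown 1 did not (−0.108 to 0.152). These sets were picked after the values were seen. A grouping of the libraries under other numbers was not tested. Best with their own number correlated 4 of 9 and 2 of 6 libraries. With the number as a block, 705 genes were called for the Nfat5 knockdown, 370 were shared the same way by both knockdowns and 239 by KRN2 and the Nfat5 knockdown. Counts of changes over 2-fold aside, no other count moved by over 1.5 times. The block also brought the epithelial list of the Nfat5 knockdown past the threshold (0.0411). Depth was 36281800 to 58974600 in the knockdown experiment before scaling and 20506848 to 30244607 in the inhibitor experiment. In the simulations, changes of 1.5-fold were called in 58.2% of cases for the Nfat5 knockdown and 64.2% for KRN2. The knockdown simulation used the scaled totals, and both used a dispersion set by hand. These shares therefore do not give how often such changes would be called in these libraries.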

Other observations

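The tests of Nfat5 without scramble replicate 1, of scramble replicate 1 as the whole cause of the fall of n-R5-8s1 and of how many splits could reach a count were chosen after the result was seen, and all others of this part before. Interferon-stimulated genes went both ways in the Smad3 knockdown, with 7 of 28 higher and 5 lower (9 and 6 adjusted over the list alone, camera adjusted p = 0.483, fry 0.0323, higher). The chemokine Cxcl10 (0.99), Irf7 (0.96) and Oas3 (1.84) rose and the GTPase Gbp2 fell (−0.67). In the Nfat5 knockdown 1 rose and 1 fell (camera 0.322), and with KRN2 7 of 20 fell, Gbp2 (−1.34) and Oasl2 (−1.06) among them, and 1 rose, Bst2 (0.80; 1 and 9 adjusted over the list alone, camera 0.0958, fry 0.00286). MHC class I genes fell in 6 of 13 cases with KRN2 and rose in 2 (7 and 2 adjusted over the list alone; camera 0.0158, and adjusted p = 0.336 with an estimated correlation), with H2-Q4 at −0.91 and H2-T23 at −0.63. In the Smad3 knockdown H2-T23 rose (0.91) and the list gave 1 of 15 higher and 3 lower (4 and 5 adjusted over the list alone, camera 0.854, with a median of 0.02 and a mean of −0.12), and in the Nfat5 knockdown 1 higher and 0 lower (1 and 1 adjusted over the list alone, camera 0.520). Of the S100 list, 6 of 13 members were higher in the Smad3 knockdown, S100a1 (0.65) and S100a10 (0.33) among them, and S100a4 alone was lower (7 and 2 adjusted over the list alone, camera 0.350). In the Nfat5 knockdown S100a4 alone of 13 passed (1 and 1 adjusted over the list alone, camera 0.568).

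NRF2 targets split in the Smad3 knockdown, 8 of 20 higher and 4 lower (camera 0.442, fry 0.00191, higher), with Gsta4 at 1.22 and haem oxygenase, Hmox1, at −1.18. Hmox1 fell in the Nfat5 knockdown as well (−0.89), where the list gave 1 of 20 higher and 3 lower (camera 0.473). AhR targets rose in 4 of 7 cases with KRN2 and fell in 0 (camera 0.0158, and adjusted p = 0.183 with an estimated correlation), Ugt1a6a (1.19) and Nqo1 (1.79) among them. In the Smad3 and Nfat5 knockdowns AhR targets gave 3 higher and 2 lower and 0 higher and 1 lower of 6 (4 and 2, and 1 and 1, adjusted over the list alone; camera 0.639 and 0.980, the latter with a median of 0.03 and a mean of −0.02). Of p53 targets, 6 of 22 rose and 7 fell with KRN2 (7 and 7 adjusted over the list alone, camera 0.839, median 0.09, mean −0.04), where Pmaip1 fell (−1.07) and Trp53inp1 rose (0.66). Trp53inp1 rose in the Smad3 knockdown too (1.11; list 3 of 21 higher and 6 lower, 4 and 7 adjusted over the list alone, camera 0.483, median 0.05, mean −0.03), and in the Nfat5 knockdown 2 rose and 5 fell (4 and 5 adjusted over the list alone, camera 0.283). Glycolysis gave 10 of 20 higher and 3 lower in the Smad3 knockdown (camera 0.134, 0.0138 without scramble 1 and 0.0294 after quantile normalisation), with Pfkfb3 at 0.70 and the lactate exporter Slc16a3 at −0.67. In the Nfat5 knockdown 3 rose and 1 fell (5 and 1 adjusted over the list alone, camera 0.0605, 9.4e-04 without scramble 1, 0.0415 without Nfat5 knockdown 3 and 0.0207 after quantile normalisation), Pgk1 (0.40) among those that rose, and with KRN2 7 rose and 6 fell (8 and 6 adjusted over the list alone, camera 0.498). Of the mitochondrial genes 0 of 13 passed in either knockdown (camera 0.578 for Nfat5 and 0.483 for Smad3), and with KRN2 3 of 12 rose and 0 fell (2 and 0 adjusted over the list alone, camera 0.113, 9.3e-04 without DMSO 3), mt-Nd1 (0.52) and mt-Co1 (0.49) among them. In the Nfat5 knockdown integrated stress response genes gave 0 of 25 higher and 3 lower (camera 0.0917, 0.0415 without Nfat5 knockdown 3, fry 0.0304) and ribosome biogenesis 0 of 25 higher and 4 lower (camera 0.511, median 0.01, mean −0.01). Fatty acid synthesis with KRN2 gave 3 of 14 higher and 7 lower (3 and 8 adjusted over the list alone, camera 0.115, 0.0289 without DMSO 3). The subunit mt-Co2 read 0.770 ± 0.22 CPM with KRN2 and 0.415 ± 0.18 with DMSO, against 6859 ± 1098 for mt-Co1 with DMSO (log2 fold change 0.88, adjusted p = 0.0731; 0.0337 without DMSO 3 and 0.0383 without KRN2 3), while in the knockdown table mt-Co2 stood at 49422 ± 9925 normalised counts in the Nfat5 knockdown.

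Nfat5 was lower in all 3 Nfat5 knockdown libraries and yet short of the threshold, with scramble replicate 1 (6159) far above replicates 2 (3831) and 3 (3456). A bias of scramble 1 towards long transcripts is argued against: 349 genes with an exonic length near that of Nfat5 (18378 bases) deviated there by a median of 0.0880 ± 0.0127 (log2, standard error), against 0.759 for Nfat5. A high reading of Nfat5 in that library alone may contribute and stays open. Without it the log2 fold change was −0.32 ± 0.15 (adjusted p = 0.254), 55.8% of its size, and the 3 knockdown libraries still lay below all others. At the transcript level the knockdown was partial at most, since its libraries still read 2895 to 2958 against 3456 to 6159 in scramble. Loss of protein beyond that of transcript was not tested.

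KRN2 and the Nfat5 knockdown gave fold changes that were nearly uncorrelated across genes (r = 0.0247). A different baseline in the experiments could lower r and stays open: scramble and DMSO levels correlated at a Spearman rho of 0.945, and among the 9088 genes whose levels lay within 1.5 times r was 0.114 ± 0.0167 (bootstrap standard error), between the values set in advance for and against it. Noise in the small changes of the Nfat5 knockdown stays open too, with r = 0.0911 ± 0.0383 among the 1602 genes called there. That r lay well below the value set in advance for noise, and was not clearly below the value set against it. Among the 911 genes called in both experiments r was 0.105 ± 0.0475. These standard errors take genes as independent, which they are not. Effects of KRN2 on other proteins, and effects of lost NFAT5 protein that an inhibitor does not share, are biological explanations the design leaves. So is the Nfat5 transcript that remained in the knockdown, and none of these was tested as a cause.

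Of 33 tested small structural RNAs, 23 in the Nfat5 and 24 in the Smad3 knockdown had a log2 fold change below 0 against scramble, with medians of −0.53 ± 0.24 and −0.43 ± 0.15, but most did not pass. Called lower were 4 (12.1%, against 4.71% of all genes) and 3 (9.09%, against 14.4% of all genes). For the Smad3 knockdown the share called lower was thus not above that of all genes. In either knockdown 0 were called higher, whereas 940 and 2556 of all 15540 genes were. How much of the fall of Rmrp came from a high reading of scramble replicate 1 stays open. Without that library at least 75.6 ± 18.5% of the fall stayed, above the 75% set in advance by less than its standard error (−1.64 in the Nfat5 and −1.32 in the Smad3 knockdown, limma adjusted p = 0.0259 and 0.0155). Scramble replicates 2 and 3 (85.1 and 58.8) still lay above all 6 knockdown libraries (19.1 to 35.7). As the whole cause for n-R5-8s1 a high reading of scramble replicate 1 is argued against: at least 80.1 ± 6.61% stayed (−1.43 and −1.31, 0.00183 and 6.2e-05), and scramble replicates 2 and 3 (1722 and 1593) lay above all 6 knockdown libraries (525 to 686). More RNA without a poly(A) tail in the scramble libraries may contribute and cannot be told apart from an effect of both knockdowns, because the library batch of each group is not given.

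Each comparison of 3 libraries with 3 was set against the other splits of its 6 libraries, 10 in all with the real one, which is too few for a share under 0.05. Only 1 split, the real one, reached its count in each case. The Nfat5 knockdown gave 1672 genes and at most 7 in another split, the Smad3 knockdown 4801 and 2, their difference 5132 and 2, and KRN2 6523 and 0. For lists past camera the real and highest other values were 13 and 9, 13 and 12, 13 and 11, and 21 and 20. The splits with 12 lists for the Smad3 knockdown and 20 for KRN2 called 0 genes. At the preset correlation the number of lists past camera thus barely set the real groups apart from mixed ones. Every other split, however, put 2 libraries of 1 group with 1 of the other on each side. It kept part of the real difference and added to the spread within its groups. The other splits are therefore not comparisons without an effect. Neither their low gene counts nor their many lists show what chance would give. For genes moved the same way by both knockdowns, 2 of 100 splits of the 9 libraries gave as many as the real split (773). This leaves chance open, because of the 99 other splits 1 called 773 genes or more in both comparisons and the rest could not have reached the count. That split, with 2642, took the Smad3 knockdown libraries as the controls, a structure of the samples, and the next highest gave 8. Of 100 pairs of splits for KRN2 and the Nfat5 knockdown, 1, the real pair, gave 544, and the highest other was 1. This too leaves chance open, since the other pairs called at most 7 genes in the comparison with fewer.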
